A study of Mus musculus with 4 samples.

How the data were processed

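RNA sequencing of total RNA was carried out on 4 mouse libraries, 1 per group. The groups were whole embryos at embryonic day 11.5 (E11.5) labelled Adar1-/-, whole embryos at E11.5 labelled Adar1-/- Mavs-/-, embryonic livers at E15.5 labelled Adar1-/- and embryonic livers at E15.5 labelled Adar1-/- Mavs-/-. The strain label differed between the tissues (C57B16/N for embryos and C57B6/J for livers) and was the same within each tissue. RNA was extracted with Trizol and made into libraries by standard Illumina protocols, per the labels' protocols. Whether the libraries keep the strand is not given in the sources used here, so reads of a gene and of an overlapping antisense gene may not be separated.

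The mm9 build, TopHat 1.4.0 and Cufflinks 2.2.1 are named without roles, per the submitters' processing notes, beside a tool that tests read counts, no output of which was used here. The deposited values are FPKM (fragments per kilobase of transcript, relative to the mapped fragments of the library), 1 value per isoform and library, with a lower and an upper confidence bound and a status for each, per the file headers. The bounds cover the estimation within a library only. Each deposited coverage value is the mean read depth of an isoform and was a fixed multiple of its FPKM within a library. Isoforms carry either a reference Ensembl transcript identifier or an identifier of a transcript assembled from the reads. The options of the assembly, and whether duplicate or multiply mapped reads were kept, are not given in the sources used here.

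The tables held 24127 isoforms for the embryo Adar1-/- library and 30090 for the embryo Adar1-/- Mavs-/- library, and 301774 and 289174 for the liver libraries labelled Adar1-/- and Adar1-/- Mavs-/-. The embryo values span chromosomes 10 and 11 and a first part of chromosome 12, to 11.7 Mb in the Adar1-/- library. The embryo Adar1-/- Mavs-/- values go on over all of chromosome 12 and to 44.7 Mb of chromosome 13. Embryo comparisons therefore cover the shared part, and other chromosomes were not analysed here for embryos, which leaves out Adar on chromosome 3 and Mavs on chromosome 2. Read totals are not given in the sources used here. Coverage per FPKM, which scales with depth, was 3.48 and 5.62 in the embryo libraries and 8.58 and 7.13 in the liver libraries, with Adar1-/- first. The median distance from a gene's value to its bound, as a percentage of the value, was 19.5, 14.1, 10.2 and 11.7 in the same order for genes from 1 to 5 FPKM, and 7.26, 6.46, 4.36 and 4.83 for genes of at least 5 FPKM.

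Gene symbols came from the GENCODE M21 annotation through the Ensembl transcript identifiers, of which 90.2%, 88.7%, 86.7% and 86.7% matched in the same order. No coordinates were taken from that annotation, which belongs to another build, and all positions are those of the deposited mm9 values. An assembled isoform was counted under the symbol in its Cufflinks gene whose reference isoforms it overlapped best. The FPKM of a symbol's isoforms were summed, and the bounds' distances were combined as the root of their summed squares. Isoforms without a symbol held 42.2%, 63.9%, 42.0% and 39.9% of the FPKM weighted by isoform length and entered no gene value.

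The value compared was the log2 ratio of FPKM plus a pseudocount of 1, the library labelled Adar1-/- Mavs-/- over the library labelled Adar1-/- of the same tissue. This scale understates differences of genes with low values. Values of the library labelled Adar1-/- Mavs-/- were first multiplied by a single factor that set the median log2 ratio of genes with at least 5 FPKM in both libraries to 0. The factor was 1.34 in embryos, from 973 genes, and 0.995 in liver, from 6890 genes. Genes with at least 1 FPKM in either library were counted, and a log2 ratio of at least 1 in size was called 2-fold. With 1 library per group there is no replicate check of any difference, no p-value was computed, and every value compares 2 libraries rather than 2 genotypes. A count of 2-fold genes is a count by size and uses no replicate error. An exact 0 can be a failed estimate of an isoform, so such genes are said to be listed at 0 and are given no fold.

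A set of 34 gene lists, the rule for named genes, the scaling, the filter and most alternatives were fixed before the data were examined. The lists cover innate immune signalling (interferon-stimulated genes, RNA and DNA sensors with the MAVS pathway, interferons and cytokines, MHC class I antigen presentation, NF-kB targets), stress (p53 targets and apoptosis, the integrated stress response, ER chaperones and the unfolded protein response, hypoxia and glycolysis, immediate early and heat shock genes) and RNA editing (editing enzymes and partners, known ADAR recoding sites). Blood lists cover adult globin and late erythroid genes, embryonic globins, erythroid transcription factors, stem and progenitor cells, granulocytes, macrophages, megakaryocytes, and lymphoid and mast cells. Tissue lists cover hepatocytes, cholangiocytes and hepatoblasts, stellate, mesothelial and fibroblast cells, endothelium, neural progenitors, neurons, heart muscle, skeletal muscle, cartilage and limb, posterior and anterior Hox genes, cell cycle, yolk sac and placenta, and X-inactivation with Y-linked genes. A list's median log2 ratio was set against 10000 random lists of the same size matched on expression in 20 bins, and a list was said to stand apart outside the central 95% of them. This percentile describes these libraries and is not a test of genotype. Intervals of medians are order-statistic 95% intervals over genes. For lists of 5 counted genes the interval is the full range of the members and falls short of 95%. Lists with fewer than 5 counted members are given by their members' values only.

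Adar and Mavs were reported first. In each tissue the 10 genes with the highest and the 10 with the lowest log2 ratio were named among genes with at least 5 FPKM in either library whose isoforms above 0 all had the status OK and numbered at least 1 in both libraries. Small RNA symbols, predicted genes and clones with Gm, Rik or clone names and genes whose longest transcript was under 300 bases were left out of that ranking. From each list up to 4 members in the direction of its median and up to 2 in the other were eligible to be named. Across tissues up to 10 genes at least 2-fold the same way and up to 10 in opposite ways were eligible. A gene named outside these rules is said to have been chosen after its values were seen.

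The procedure was tested on simulated data that used the Adar1-/- gene levels, random noise with a log2 SD of 0.509 in embryos (2645 genes) and 0.577 in liver (20153 genes), and 200 changed genes. For a true factor of 1.333 it recovered 1.333 in embryos and 1.25 in liver. Genes changed by a log2 value of 2 were called in 97.0% and 93.0% of cases, those changed by 3 in 100% in both tissues, and unchanged genes in 1.9% and 4.4%. Of 15 lists of 13 genes shifted by -1, 14 stood apart in embryos and 15 in liver, against 3.0% and 4.0% of 200 unshifted lists. These rates describe the simulated data only and are not error rates of the counts below. Noise was random in the simulation, whereas liver log2 ratios followed GC content, with a Spearman coefficient of -0.42. In liver, 1040 of 13847 counted genes also had FPKM in a single library only. Changed genes and shifted lists were drawn only from genes well above the filter of 1 FPKM. Recovery was therefore not measured for genes with low values. It may be lower for them, as the pseudocount understates their differences.

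Alternatives fixed in advance were pseudocounts of 0.1 and 5, no filter and a filter of 5 FPKM, FPKM as deposited, TPM, TPM without globin, mitochondrial and the 20 most abundant genes, an upper quartile factor, the most abundant reference isoform alone, isoforms of status OK only, transcripts of at least 300 bases only, genes whose bounds do not overlap, random lists not matched on expression, list members shared with another list left out, and Spearman's coefficient. TPM here means a factor that gives both libraries of a tissue the same sum of gene values. Isoforms without a symbol and genes outside the shared part do not enter that sum, so it differs from TPM over a whole library. Alternatives chosen after seeing the data left out genes listed at 0, used reference isoforms only, weighted isoforms by length, kept Cufflinks genes with a single symbol, kept protein-coding genes, or subtracted from each log2 ratio the median of its GC content bin (20 bins, GC from GENCODE M21 transcripts). Computation used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.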

Results

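Total RNA was sequenced from mice labelled as lacking Adar1 alone or Adar1 together with Mavs, in whole embryos at E11.5 and in embryonic liver at E15.5, with 1 library in each of the 4 groups. ADAR1, the product of the mouse gene Adar, converts adenosine to inosine in double-stranded RNA, and MAVS is the adaptor protein through which the RNA sensors RIG-I and MDA5 signal. By the labels, the comparison in each tissue asks how the transcriptome of a mouse without Adar1 differs when Mavs is lost as well. Log2 ratios are those of the library labelled Adar1-/- Mavs-/- over the library labelled Adar1-/-, on the scale of FPKM plus 1 after scaling, and higher or lower refers to the library labelled Adar1-/- Mavs-/- unless another is named. No group has a replicate, so no difference could be set against a spread between animals. The FPKM bounds given in places cover estimation within a library only.

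Coverage per FPKM, which follows depth, was 3.48 in the embryo Adar1-/- library, 5.62 in the embryo Adar1-/- Mavs-/- library, 8.58 in the liver library labelled Adar1-/- and 7.13 in the liver library labelled Adar1-/- Mavs-/-. Genes of at least 1 FPKM numbered 1833 and 1771 in the embryo libraries, whose shared part is chromosomes 10 and 11 and the first 11.7 Mb of chromosome 12, and 13022 and 12436 in the liver libraries. Other scalings shifted embryo log2 ratios, before the pseudocount, by -0.42 with FPKM as deposited, by -0.94 with TPM over the shared named genes and by 0.14 with an upper quartile factor. In liver the shift was -0.32 with TPM, -0.22 with TPM without the most abundant genes and 0.13 with an upper quartile factor. The pseudocount makes these shifts smaller for genes with low values. Single log2 ratios of about these sizes can therefore change sign with the scaling, mainly in genes with high values, whereas a list and its random lists move together.

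Adar was read first, because it checks the labels. In liver the gene spans 89518944 to 89557368 of chromosome 3 (mm9), 38425 bases. Spans were read from isoforms counted under Adar or without a symbol, and isoforms counted under another symbol were not used. In the liver library labelled Adar1-/-, 0 of its 8 reference isoforms were above 0, and a stretch of 16246 bases from 89538115 to 89554360, 42.3% of the gene, was spanned by no such isoform above 0. Assembled isoforms on both sides of that stretch gave Adar 5.56 FPKM (bounds 5.28 to 5.84). In the liver library labelled Adar1-/- Mavs-/-, 3 of the 8 reference isoforms were above 0 with 2.82 FPKM between them, no base of the gene was left unspanned, and Adar had 4.09 FPKM (bounds 3.84 to 4.34). The reference isoform over the whole gene, ENSMUST00000098924, had 1.11 FPKM there. Assembled isoforms inside the stretch, from 89544415 to 89545908 and from 89546038 to 89547168, had 1.62 and 1.04 FPKM.

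**Figure D1:**
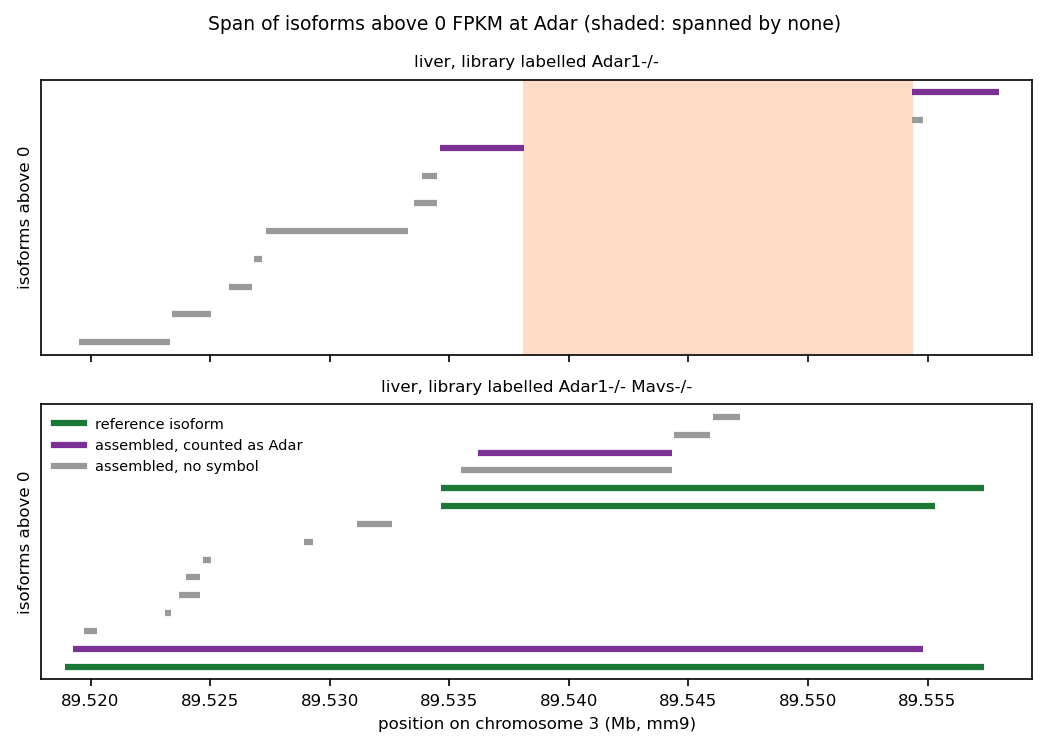
Position on chromosome 3 (mm9, Mb) of the isoforms above 0 FPKM at Adar in the 2 liver libraries, one line per isoform, with reference isoforms, assembled isoforms counted under Adar and assembled isoforms without a symbol in different colours. Isoforms counted under another symbol are not drawn. The shaded stretch of 16246 bases is spanned by none of the drawn isoforms in the library labelled Adar1-/- and is spanned in the library labelled Adar1-/- Mavs-/-. Lines include introns.

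Adar thus differed between the liver libraries, and no unspanned stretch marks its loss in the library labelled Adar1-/- Mavs-/-. Spans run from the first to the last base of an isoform and include introns, so a loss of some exons there could stay unseen. That library may go against its label, and every liver direction below is a direction between libraries with these labels. Mavs spans 131059799 to 131073761 of chromosome 2. It had 7.26 FPKM (bounds 6.64 to 7.88) in the liver library labelled Adar1-/- and 9.91 FPKM (bounds 9.13 to 10.69) in the library labelled Adar1-/- Mavs-/-, a log2 ratio of 0.40, with no unspanned base in either. How the Mavs allele was made is not given in the sources used here, so an RNA level outside a deleted part would check nothing. Mice without ADAR1 are known to die in mid-gestation, before E15.5, and how livers labelled Adar1-/- were obtained at that age is not given in the sources used here. In embryos Adar and Mavs were not analysed here.

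In E11.5 embryos, the interferon-stimulated genes of the shared part were far lower in the Adar1-/- Mavs-/- library than in the Adar1-/- library. The list has 89 genes, of which 14 were in the values of both embryo libraries, so genes such as Isg15 and Ifit1 were not read. Of the 13 counted, 12 were at least 2-fold lower and the other, Stat2, named after its value was seen, had a log2 ratio of -0.92. The median log2 ratio was -3.36 (interval -5.02 to -2.20), at the 0.0 percentile of matched random lists, whose central 95% ran from -0.53 to 0.16. Random lists were not matched on position, and several of these genes lie near each other on chromosome 11. Irgm1, an interferon-inducible GTPase (chromosome 11, 48675470 to 48685185), had 69.9 FPKM (bounds 67.3 to 72.6) in the Adar1-/- library and 0.584 (bounds 0.305 to 0.863) in the Adar1-/- Mavs-/- library. Igtp, another GTPase of that family (chromosome 11, 58013058 to 58021093), had 46.6 and 1.04 FPKM, a log2 ratio of -4.55. Ifi35 had 31.4 FPKM in the Adar1-/- library and was listed at 0 in the other. Rnf213, a ubiquitin ligase, had 90.0 and 1.34 FPKM, but its log2 ratio was 1.21 when only isoforms of status OK were used, and the list median was -2.53 in that setting.

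**Figure D2:**
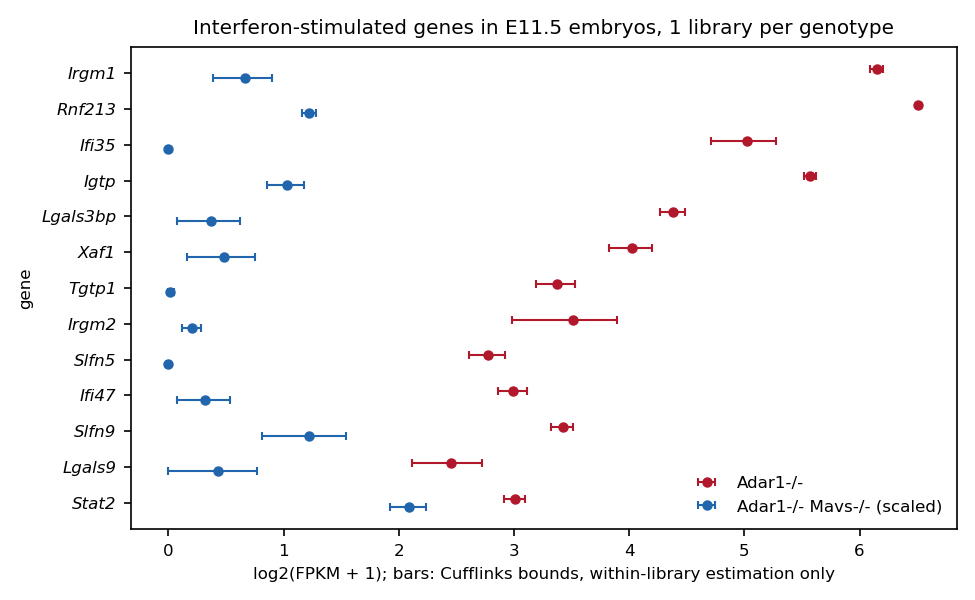
log2(FPKM + 1) of the 13 counted interferon-stimulated genes in the Adar1-/- embryo library (red) and the Adar1-/- Mavs-/- embryo library (blue, scaled), 1 library each, with the Cufflinks bounds as bars. Each gene lies further left in the Adar1-/- Mavs-/- library, from a log2 ratio of -5.49 for Irgm1 to -0.92 for Stat2.

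The 5 counted sensor and MAVS pathway genes did not stand apart as a group in embryos, with a median of -0.17, at the 51.6 percentile. Their values ran from -3.05 to 0.00, a range too wide to call the group unchanged. Among them, Trim25, the ubiquitin ligase that acts on RIG-I, had 11.1 and 0.457 FPKM (-3.05, at -1.47 with reference isoforms only), and Dhx58, which encodes the RIG-I relative LGP2, had 5.97 and 0.737 FPKM. Tbk1, the kinase downstream of MAVS, was at -0.08 and Rnf135 at 0.00. The counted chemokine genes Ccl2 and Ccl12 were both at least 2-fold lower, at -1.06 and -1.23, from 1.16 and 1.89 FPKM. Tnip1, the counted NF-kB target, was at 0.67. No MHC class I, immediate early or heat shock, or X-inactivation and Y-linked gene was counted in the shared part.

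Other embryo lists with 5 counted members did not stand apart. p53 target and apoptosis genes had a median of -0.26, at the 38.4 percentile, with Mdm2 at -0.46 and Ccng1 at -0.05. Stellate, mesothelial and fibroblast genes had a median of -0.22, at the 34.7 percentile, although Col1a1, a collagen chain, had 77.9 and 30.3 FPKM (-1.33, at -0.10 with reference isoforms only). Cell cycle genes had a median of -0.42, at the 4.9 percentile, with Aurkb at -1.31 and Birc5 at 0.48.

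Lists with fewer counted members held mostly values within 2-fold. Integrated stress response genes ran from -0.63 (Ddit4) to 0.24 (Shmt2), and the ER genes Xbp1 and Hsp90b1 were at -0.52 and 0.01. The alpha globins Hba-a1 and Hba-a2 were the most abundant of the listed genes, at 5006 and 3852 FPKM in the Adar1-/- library and 5999 and 4140 in the other, and the embryonic globin Hba-x had 806.2 and 1139. Slc4a1 was at 0.23, and the erythroid regulators Bcl11a, Cited2 and Zbtb7a were at -0.58, -0.30 and -0.30. Meis1 of the stem cell list was at -0.28, Mpo of the granulocyte list at -0.21 and Ebf1 of the lymphoid list at -0.32. Megakaryocyte genes ran from -0.36 (P2rx1) to 0.40 (Itgb3). Both counted macrophage genes were at least 2-fold higher. Lyz2, which encodes lysozyme, had 0.960 and 3.99 FPKM, and Cd68 was listed at 0 in the Adar1-/- library with 1.24 FPKM in the other.

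Vtn of the hepatocyte list had 97.1 and 15.8 FPKM (-2.55, at -0.26 with reference isoforms only), and Apob, which the yolk sac list also holds, was at -0.47. Cholangiocyte and hepatoblast genes ran from -1.02 (Krt19, which was at 0.78 with reference isoforms only) to 0.32 (Sox9). The endothelial genes Icam2, Pecam1, Stab2 and Ramp2 ran from 0.21 to 0.75. Neural genes ran from -0.75 (Fabp7) to 0.64 (Tlx3), heart muscle genes from -0.32 (Pln) to 0.19 (Myl7) and skeletal muscle genes from -0.94 (Myh3) to 0.60 (Myf5). Tbx4 of the limb list was at -0.60. Hoxb9 of the posterior Hox list was at 0.84, Hoxb3 and Hoxb4 of the anterior list were at 0.54 and -0.15, and Hoxb2 was listed at 0 in the Adar1-/- Mavs-/- library after 3.36 FPKM in the Adar1-/- library. Aldoc of the glycolysis list was listed at 0 in the Adar1-/- library and above 0 in the other, and the other 3 members ran from -0.55 (P4ha1) to 0.39 (Pfkl). The editing enzyme genes Adarb1, Adat2 and Adat3 were at -0.36, -0.15 and -0.24. Of the genes with ADAR recoding sites, Grik2, Cyfip2 and Ube2o were at -1.07, -1.01 and -0.45.

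Of 1944 counted embryo genes, 130 were at least 2-fold higher and 188 at least 2-fold lower in the Adar1-/- Mavs-/- library, with bounds apart for 108 and 166 of them, and 1626 lay within 2-fold. Among the higher genes 56 were listed at 0 in the Adar1-/- library, and among the lower genes 65 in the other. A value listed at 0 can have both bounds at 0, as for Ifi35. Bounds apart then follow almost by construction and add no support for such genes. The higher share of the 2-fold genes, 40.9%, was 20.4% with FPKM as deposited, 7.07% with TPM and 36.9% with TPM without the most abundant genes. It was 48.8% with an upper quartile factor and 47.9% after centring within GC bins. Among 576 eligible genes the lowest log2 ratios included Igtp, Irgm2 (-3.30), Tgtp2 (-3.24), Trim25, Ncoa7 (-2.15, at -1.07 with reference isoforms only), Myo19 (-2.11, at 0.00 with reference isoforms only) and Dhx58. The others were Cnksr3 (-2.71), Hap1 (-2.12) and Cpsf6 (-1.77), which with reference isoforms only were at 0.49, 0.25 and 0.05. The highest were Cct6b and Tob1 (2.37 and 2.34, but -0.28 and -2.26 with reference isoforms only), the ribosomal protein pseudogenes Rpl27a-ps1 (2.09), Rpl27-ps2 (1.49) and Rps15a-ps6 (1.42), Pcyt2 (1.52), Fam171a2 (1.49), and Pold2 (1.77), Polr2e (1.39) and Akap7 (1.31), which with reference isoforms only were at 0.31, 0.32 and 0.11. Pseudogenes share sequence with their parent genes, so their values are uncertain. With reference isoforms only, 5 of the 10 higher and 6 of the 10 lower genes were still at least 2-fold the same way.

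In E15.5 liver, the lowest list median was that of skeletal muscle genes. All 11 counted skeletal muscle genes were at least 2-fold lower in the library labelled Adar1-/- Mavs-/-, with a median log2 ratio of -2.94 (interval -3.66 to -2.09). Myl1, a myosin light chain (chromosome 1, 66970869 to 66991978), had 28.2 FPKM (bounds 26.7 to 29.6) in the library labelled Adar1-/- and 0.0845 in the other, and Ckm, the muscle creatine kinase (chromosome 7, 19996443 to 20006932), had 11.9 and 0.0208. Of 12 heart muscle genes 9 were at least 2-fold lower, with a median of -1.96 (interval -2.49 to -0.86), among them Actc1 at -3.62. Of 9 cartilage and limb genes 6 were, with a median of -1.31 (interval -1.74 to -0.86), among them Col2a1 at -1.84. Some members are also known in cells of fetal liver, such as Sox6 of the cartilage list, which the erythroid regulator list holds as well. All 3 lists lay at or below the 0.1 percentile of matched lists, and after centring within GC bins their medians were -2.59, -1.66 and -1.16, still apart.

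Integrated stress response genes, which respond to amino acid shortage and to phosphorylated eIF2alpha, were also lower in the library labelled Adar1-/- Mavs-/-. Of 23 counted, 10 were at least 2-fold lower and 0 higher, with a median of -0.96 (interval -1.63 to -0.49) at the 0.0 percentile. Trib3 (chromosome 2, 152163158 to 152169768) had 8.35 FPKM (bounds 7.84 to 8.87) in the library labelled Adar1-/- and 0.208 (bounds 0.116 to 0.300) in the other, and Nupr1 had 4.93 and 0.574. The transcription factor genes Cebpb, at 13.5 FPKM in the library labelled Adar1-/-, and Ddit3, at 5.98, were listed at 0 in the other. Phgdh of serine synthesis was at 0.42. The most abundant members, chosen after their values were seen, lay within 2-fold, with Atf4 at -0.34, Psat1 at -0.29, Asns at 0.20 and Ppp1r15a at -0.47. ER chaperone and unfolded protein response genes had a median of -0.51 (18 counted, 4 lower and 1 higher by 2-fold, 0.0 percentile), with Sdf2l1 at -2.69 (-0.34 with reference isoforms only) and Pdia3 at -1.29 but Hsp90b1 at 0.85. Dnajb9 was at 1.12 with all isoforms summed and at -1.12 with reference isoforms only.

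Interferon-stimulated genes had a smaller median difference between the liver libraries as labelled than between the embryo libraries, a contrast that was not tested and that sets genes of the whole genome against those of the part shared in embryos. Of 64 counted, 12 were at least 2-fold lower and 2 higher in the library labelled Adar1-/- Mavs-/-, with a median of -0.34 (interval -0.52 to -0.10). This lay at the 6.2 percentile of matched lists, inside their central range of -0.38 to -0.03, and after centring within GC bins the median of -0.25 lay at the 0.4 percentile, outside it. The 13 genes counted in embryos, a set read in liver only after the values were seen, had a liver median of -0.83 (interval -1.13 to -0.37, 0.2 percentile), with 12 of them below 0 and 4 at least 2-fold lower. Isg15, a ubiquitin-like protein induced by interferon (chromosome 4, 155573533 to 155574927), had 7.30 FPKM (bounds 6.56 to 8.05) in the library labelled Adar1-/- and 1.72 (bounds 1.31 to 2.12) in the other. Ifi47, Trim34a and Shisa5 had 2.10, 3.08 and 3.16 FPKM in the library labelled Adar1-/- and were listed at 0 in the other. Eif2ak2, which encodes the RNA-activated kinase PKR, and Trafd1 were listed at 0 in the library labelled Adar1-/- and had 32.2 and 3.60 FPKM in the other.

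Other immune lists lay inside the range of random lists in liver. Sensor and MAVS pathway genes had a median of -0.22 (25 counted, 35.0 percentile), with Ifih1, which encodes MDA5, at -0.91 and Ifnar2 at 1.08. Interferon and cytokine genes had a median of -0.19 (6 counted, 58.7 percentile), with Cxcl1 at -1.12 and Il1a listed at 0 in the library labelled Adar1-/- with 4.26 FPKM in the other. MHC class I genes had a median of -0.19 (19 counted, 35.2 percentile), with Tap1 at -1.26 (-0.63 with reference isoforms only), H2-Q10 at -1.08, and Psmb10 and H2-T10 listed at 0 in the library labelled Adar1-/-. NF-kB targets had a median of -0.49 (14 counted, 6 of them at least 2-fold lower, 4.5 percentile), with Tnip1 at -1.89, Icam1 at -1.57 and Relb at -1.50. After centring within GC bins that list had a median of -0.37, at the 1.6 percentile.

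Macrophage genes, megakaryocyte genes and cell cycle genes stood above the random lists in the liver library labelled Adar1-/- Mavs-/-. The macrophage median was 0.55 (23 counted, interval 0.16 to 0.78), with Adgre1, which encodes F4/80, at 5.35 and 11.8 FPKM, Ctss at 9.11 and 21.4 (a log2 ratio of 1.15, at 0.38 with reference isoforms only), and Vsig4 at 0.00858 and 1.92. Fcgr3 went the other way at -1.67, but was at 4.15 with reference isoforms only. The megakaryocyte median was 0.45 (13 counted, interval -0.25 to 0.79), with the platelet chemokine genes Ppbp at 1.26 and Pf4 at 0.87, and Thbs1 at -0.55. Both lists were at a percentile of 100. The cell cycle median was 0.36 (34 counted, interval -0.03 to 0.66, 99.7 percentile), with Top2a at 1.06 and Cenpe at 1.07 but Cdc20 at -1.10. Nusap1 was at 1.31, and at -5.58 when only isoforms of status OK were used.

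The red cell lists with at least 5 counted genes did not stand apart before GC centring. Adult globin and late erythroid genes had a median of 0.22 (31 counted, 82.8 percentile), with Epb42 at 1.18 and Alad at -0.79, and centring within GC bins moved it to 0.45, at the 99.5 percentile. Erythroid regulators had a median of -0.07 (16 counted, 29.0 percentile), with Zbtb7a at -1.39 and Kit at -1.08. Of the 3 embryonic globins, too few to set against random lists, 2 were at least 2-fold higher. Hbb-y had 83.4 and 303.1 FPKM, Hbb-bh1 had 11.7 and 53.7, and Hba-x had 8.46 and 9.57. Stem and progenitor genes had a median of -0.10 (19 counted, 67.7 percentile), with Spi1 at -1.42. Granulocyte genes had a median of -0.28 (19 counted, 9.1 percentile), with Mpo at -0.93, and Prtn3 at 72.5 FPKM in the library labelled Adar1-/- and listed at 0 in the other. Lymphoid and mast cell genes had a median of 0.09 (12 counted, 93.4 percentile), with Il7r at 1.25.

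Among cells of the liver itself, hepatocyte genes had a median of -0.13 (49 counted, interval -0.41 to 0.07), below the random range of -0.01 to 0.29 at the 0.1 percentile. Centring within GC bins moved this median to 0.03, still below a random range of 0.10 to 0.42, and against random lists not matched on expression the list lay at the 46.0 percentile. Alb, which encodes albumin, had 4787 and 6617 FPKM, Trf, which encodes transferrin, had 2347 and 1184, and Dlk1 had 135.4 and 49.9. Stellate, mesothelial and fibroblast genes had a median of -0.59 (25 counted, interval -0.96 to -0.36, 0.1 percentile), with the collagen gene Col1a2 at 79.1 and 19.7 FPKM, Mgp at -3.53 (-1.20 with reference isoforms only) and the muscle filament gene Des at -1.89, while Pdgfrb was at 0.29. Endothelial genes had a median of -0.63 (21 counted, 0.4 percentile), with Plvap at -1.15, and Egfl7 and Ramp2 listed at 0 in the library labelled Adar1-/- Mavs-/-. Centring within GC bins moved the endothelial median to -0.29, at the 3.7 percentile, inside the random range. The stellate and endothelial lists were lower together with the muscle and cartilage lists. Cholangiocyte and hepatoblast genes had a median of -0.50 (9 counted, 11.8 percentile), with Epcam at -0.83. Yolk sac and placenta genes had a median of 0.11 (7 counted, 52.9 percentile), with Ttr at 0.15.

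Hypoxia and glycolysis genes had a median of -0.55 (24 counted, interval -0.69 to -0.08, 0.1 percentile), with Pgam1 at -1.23 and Aldoa at -1.10. Genes with ADAR recoding sites had a median of -0.52 (13 counted, 1.5 percentile) with 0 at least 2-fold either way, Tmem63b at -0.77 and Azin1 at 0.36. Centring within GC bins moved these medians to -0.21 and -0.22, at the 3.4 and 6.2 percentiles, inside the random range. Immediate early and heat shock genes had a median of -0.39 (22 counted, 4.0 percentile), with Hspa1b at -3.51, Hspa1a at -2.22 and Jund at -1.91, and Hspe1 at 3.72 but at -1.69 with isoforms of status OK only. p53 target and apoptosis genes had a median of -0.21 (27 counted, 38.9 percentile), with Cdkn1a at -1.27 and Casp1 at 1.55 (0.10 with reference isoforms only). RNA editing enzymes and partners had a median of -0.16 (17 counted, 46.0 percentile), with Stau2 at -1.55 and Zfr at 0.63. Neural progenitor genes ran from -0.92 (Fabp7) to -0.03 (Lhx2) and neuron genes from -1.28 (Stmn2) to -0.73 (Map2). Hoxa5 of the anterior Hox list was at -0.76, and no posterior Hox gene was counted. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were above 7 FPKM in both liver libraries, with log2 ratios from 0.31 to 0.47.

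**Figure D3:**
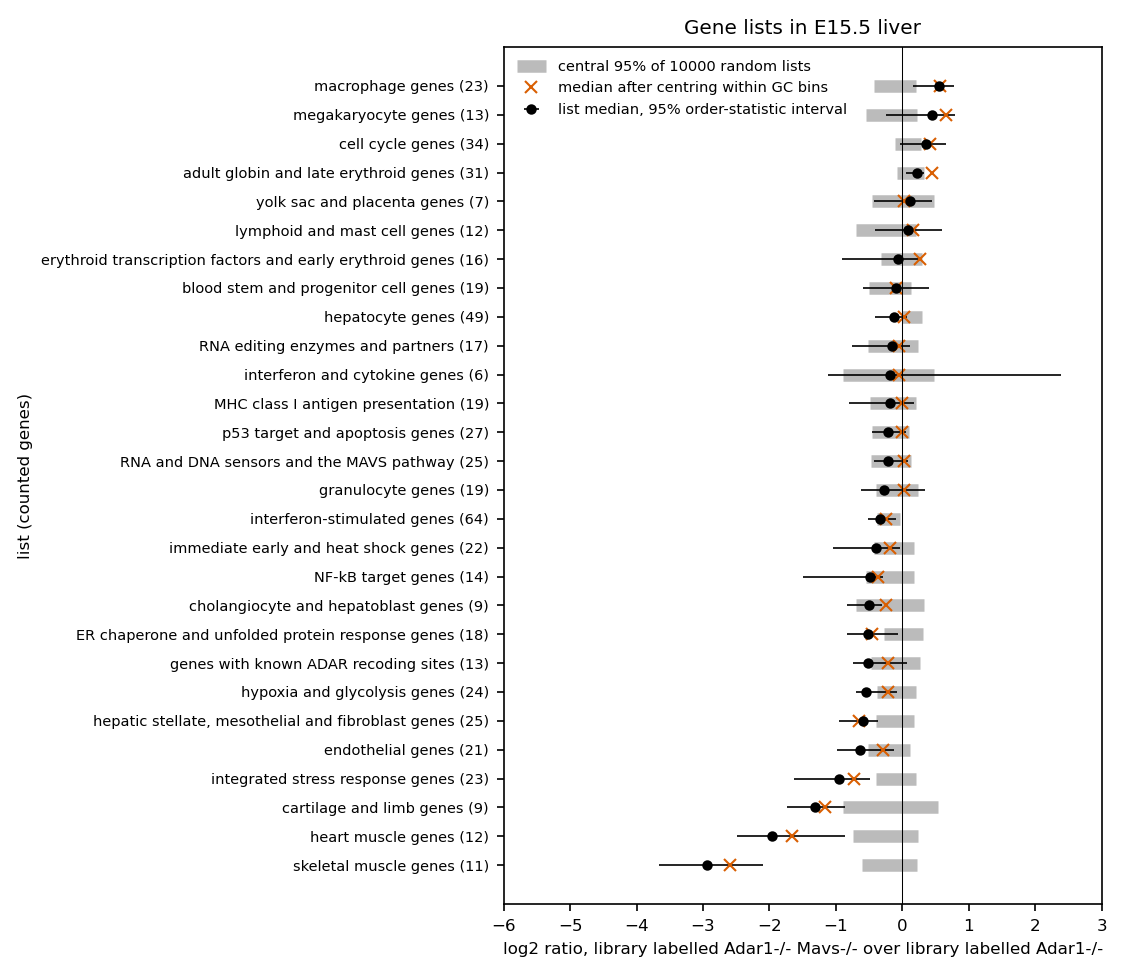
Median log2 ratio of each gene list with at least 5 counted genes in liver, library labelled Adar1-/- Mavs-/- over library labelled Adar1-/- (black points, with 95% order-statistic intervals over genes), the median after centring within GC bins (orange crosses) and the central 95% of 10000 random lists matched on expression (grey bars). The skeletal muscle list lies lowest, at -2.94, and the macrophage list highest, at 0.55.

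Of 13847 counted liver genes, 903 were at least 2-fold higher and 1349 at least 2-fold lower in the library labelled Adar1-/- Mavs-/-, with bounds apart for 762 and 1212, and 11595 lay within 2-fold. Of the higher genes 560 were listed at 0 in the library labelled Adar1-/-, and of the lower genes 480 in the other. Where the bounds of such a value are 0 as well, as for Psmb10, bounds apart add no support. The higher share of the 2-fold genes, 40.1%, was 23.8% with TPM, 28.2% with TPM without the most abundant genes and 53.3% after centring within GC bins. Of the 28 lists with at least 5 counted genes, 13 stood apart, 10 of them lower and 3 higher, and 10 of the 13 also did after GC centring. After GC centring 3 others stood apart as well, the interferon-stimulated, NF-kB and adult globin and late erythroid lists, at the 0.4, 1.6 and 99.5 percentiles. Among 2908 eligible genes the lowest were Myl1, Ckm, Actc1, Myh3 (-3.17) and Myl4 (-2.93) of muscle, the splicing factor gene Sfpq (133.9 and 9.17 FPKM), Mgp, Hspa1b, Lars2 (1376 and 169.3 FPKM, at 0.00 with reference isoforms only) and Hspb11 (-2.71, at 0.05 with reference isoforms only). The highest were Rpp21 (3.69), Scrn3 (3.66), Hbb-bh1 (2.10), Tbxa2r (2.16, at -0.33 with reference isoforms only), Nostrin (1.96, at -0.34 with isoforms weighted by length) and Pspc1 (1.91, at 0.00 with reference isoforms only). With isoforms weighted by length Rpp21 and Scrn3 were at 0.43 and 0.24. Fibp (2.72), Snx20 (2.70), Zmat2 (2.38) and Sdhaf4 (2.08) were also among them but turned to -1.21, -1.08, -0.16 and -0.18 with reference isoforms only, under which 4 of the 10 higher and 8 of the 10 lower genes were still at least 2-fold the same way.

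The liver log2 ratios followed GC content. Across 12807 genes, which are not independent replicates, the Spearman coefficient of log2 ratio and GC content was -0.42, and the median was 0.28 in the 10% of genes with the lowest GC content and -0.48 in the 10% with the highest. With gene length the coefficient was -0.16. In embryos the coefficients over 1823 genes were 0.05 for GC content and -0.27 for length, with medians of 0.25 in the 10% shortest and -0.33 in the 10% longest genes.

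**Figure D4:**
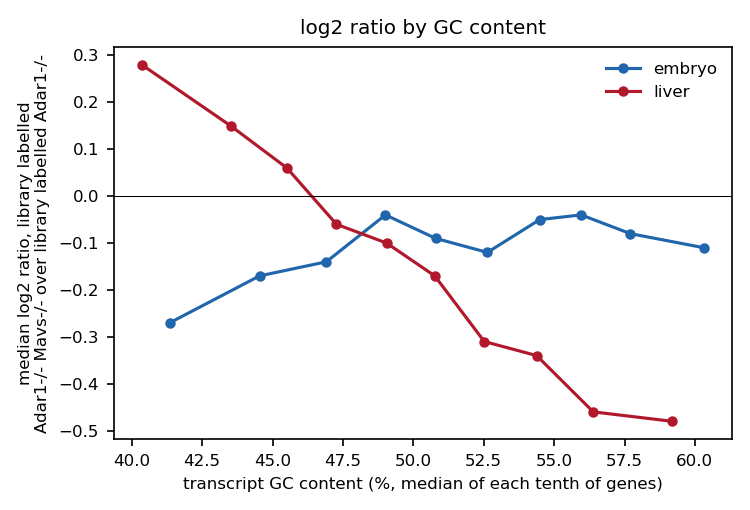
Median log2 ratio, library labelled Adar1-/- Mavs-/- over library labelled Adar1-/-, in 10 equal groups of the counted genes by transcript GC content (%), for embryo (blue) and liver (red). The liver line runs from 0.28 to -0.48, and the embryo line begins at -0.27 and ends at -0.11.

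Across the 1568 genes counted in both tissues, embryo and liver log2 ratios were nearly uncorrelated, with a Pearson coefficient across genes of 0.03 (bootstrap 95% interval over genes -0.04 to 0.10) and a Spearman coefficient of 0.06. Genes at least 2-fold higher in both numbered 12, against 4.35 for independent lists, and genes at least 2-fold lower in both numbered 17, against 11.8. The interferon-stimulated genes Ifi35 (listed at 0 in the embryo Adar1-/- Mavs-/- library, -1.42 in liver) and Ifi47 (-2.68 in embryos, listed at 0 in the liver library labelled Adar1-/- Mavs-/-) were among those lower in both. So were Grn, which encodes progranulin, and Chchd10, which had 15.9 and 4.83 FPKM in the embryo Adar1-/- library, were listed at 0 in the other embryo library and were at -1.72 and -1.41 in liver. Tsfm was listed at 0 in both libraries labelled Adar1-/- and had 23.2 FPKM in the other embryo library and 5.48 in the other liver library. Opposite ways were taken by 12 genes higher in embryos and lower in liver, against 8.76 for independent lists, and by 8 lower in embryos and higher in liver, against 5.88. Snrpd3 had 20.4 and 77.0 FPKM in embryos and 31.9 in the liver library labelled Adar1-/- while listed at 0 in the other, and Myo19 had 8.57 and 1.22 FPKM in embryos and was listed at 0 in the liver library labelled Adar1-/- with 3.08 in the other. Oxld1 was listed at 0 in the embryo Adar1-/- Mavs-/- library and in the liver library labelled Adar1-/-.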

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

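Of the tests in this part, those of a swap of the liver labels and of a mislabelled liver sample were chosen after the result was seen, and those by centring within GC bins and by leaving out genes listed at 0 use alternatives chosen after seeing the data, though before the values they gave.

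Both liver labels name Adar1-/-, but only the library labelled Adar1-/- has an unspanned stretch in Adar, of 16246 bases. Spans include introns, so a loss of some exons in the other library could stay unseen. Gaps left by chance are argued against, because only 0.0815% of 1227 genes of a like level and span have such a stretch in that library alone. A swap of the 2 liver labels is argued against as the whole cause, because both labels name Adar1-/- and the unspanned part of Adar in the library labelled Adar1-/- Mavs-/- is 0.0% of the gene, but if the genotypes carry different Adar alleles a swap stays open beside them. A mislabelled sample, with an intact Adar and an intact Mavs in the library labelled Adar1-/- Mavs-/-, stays open, because Mavs was at 1.37 times its level in the other library but how its allele was made is not given in the sources used here, so its RNA level decides nothing. A different Adar allele was not tested and stays open, as does what the label Adar1-/- means in E15.5 liver, since mice without ADAR1 are known to die in mid-gestation, before that age.

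Muscle genes were lower in the liver library labelled Adar1-/- Mavs-/-, with a skeletal muscle median of -2.94. GC content is argued against as the whole cause, because the skeletal muscle median stays at -2.59 after centring within GC bins. Muscle carried along with the liver labelled Adar1-/- is a candidate explanation, since of 46 muscle genes outside the fixed lists 19 were counted and 17 of these were lower, with a median of -1.07 (interval -1.80 to -0.45, 0.1 percentile), while Pygm, Neb, Srl, Ldb3 and Cavin4 lay within 2-fold and Tnnc1 and Eno3, listed at 0 in that library, went the other way. Mylpf, named after its values were seen as the most abundant of the skeletal muscle list in that library, had 74.7 FPKM there and 8.89 in the other. An effect of genotype on muscle genes within the liver was not tested and stays open.

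Integrated stress response genes, lower in the liver library labelled Adar1-/- Mavs-/-, had a median of -0.96. GC content is argued against as the whole cause, because after centring within GC bins the median is -0.73, still at the 0.0 percentile. Genes listed at 0 are argued against as the whole cause as well, because without them the median is -0.82. Stress in the animals or during dissection, the RNA of other tissues and the genotype were not tested and stay open.

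Some signals lie outside the comparisons. The embryo Adar1-/- Mavs-/- library has 5741 isoforms above 0 on the parts of chromosomes 12 and 13 that the other embryo library's values do not cover. An isoform without a symbol on chromosome 10, from 11211873 to 11212033 in that library, had 1050000 FPKM there, and isoforms without a symbol at the same place had 119000 FPKM in the embryo Adar1-/- library, 101000 in the liver library labelled Adar1-/- and 25100 in the liver library labelled Adar1-/- Mavs-/-.

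Genes that were above 0 in all 4 libraries and at least 2-fold higher in embryos but at least 2-fold lower in liver were Cd63 (1.30 and -1.05), Gm12009 (1.90 and -1.06) and Uqcrq (1.55 and -1.07). With 1 library per group, the difference between the tissues was not tested.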

How the results depend on the processing

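Alternatives chosen after seeing the data were leaving out genes listed at 0, reference isoforms only, isoforms weighted by length, 1 symbol per Cufflinks gene, protein-coding genes only and GC bins. The embryo median of interferon-stimulated genes stayed below the random lists in all 19 alternatives, at -5.38 with pseudocount 0.1 and -1.58 with pseudocount 5, which by construction stretch and shrink ratios. The liver median of these genes stayed negative in 19 and lay below the random lists in 2, and was -0.55 with TPM. For the other lists the value compared was the median less that of the random lists, and 487 of 504 liver values stayed within the interval of the reported one. So did 68 of 69 embryo values. The 4 embryo lists have 5 counted genes each, however, and their interval is the full range of the members, so staying within it says little. The liver lists that stood apart kept their sign, while some others changed it, among them granulocyte genes (0.09 with status OK only), erythroid regulators (0.15 with GC bins), sensor and MAVS pathway genes (0.21 with FPKM of at least 5) and, in embryos, p53 target and apoptosis genes (0.09 with reference isoforms only). The liver integrated stress response, macrophage, skeletal muscle, cell cycle and stellate lists stood apart in 19 of 19 alternatives, the hepatocyte, megakaryocyte and heart muscle lists in 18 of 19, the ER list in 17 of 19, the cartilage list in 14 of 16, and the endothelial, hypoxia and ADAR recoding site lists in 15 of 19. The correlation between tissues was 0.11 without genes listed at 0.

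Counts of 2-fold genes depended on the setting. Higher embryo genes numbered 60 with pseudocount 5, 82 with FPKM as deposited, 56 with TPM, 202 with status OK only, 74 without genes listed at 0 and 63 among protein-coding genes. Lower embryo genes numbered 86 with pseudocount 5, 320 with FPKM as deposited, 736 with TPM, 298 with status OK only, 123 without genes listed at 0 and 120 with isoforms weighted by length. Higher liver genes numbered 380 with pseudocount 5, 530 with FPKM of at least 5, 1819 with status OK only, 343 without genes listed at 0 and 596 among protein-coding genes. Lower liver genes numbered 2113 and 419 with pseudocounts 0.1 and 5, 805 with FPKM of at least 5, 2168 with TPM, 869 without genes listed at 0 and 871 with GC bins. Stricter filters count fewer genes by construction, and for the others the cause was not tested.

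For named genes a reversal was counted only where the reported log2 ratio was at least 2-fold, while the totals hold all named genes. By that rule 13 of 1572 embryo values and 32 of 2961 liver values reversed. A further 349 and 833 moved outside the range that the bounds allow. Changes of sign in genes within 2-fold are not counted as reversals, so these numbers give no rate of reversal. The cause was not tested. A gene or list that an alternative leaves without enough counted values has no value there, so Cct6b in embryos and Tbxa2r in liver, at -0.28 and -0.33 with reference isoforms only but below 1 FPKM in both libraries, are not among those that reversed. The setting with the most abundant reference isoform alone overlaps with that of reference isoforms only, so like values in both are not separate checks. With the most abundant reference isoform alone the embryo values were Tob1 -2.26, Cnksr3 0.49, Hap1 0.04, Cpsf6 0.05 and Krt19 0.78, and the liver values were Fibp -1.22, Snx20 -1.08, Zmat2 -0.18, Sdhaf4 -0.20, Dnajb9 -1.13, Fcgr3 4.13, Cdh5 2.67 and Ecscr -2.22. With reference isoforms only they were Tob1 -2.26, Cnksr3 0.49, Hap1 0.25, Cpsf6 0.05 and Krt19 0.78 in embryos, and Fibp -1.21, Snx20 -1.08, Zmat2 -0.16, Sdhaf4 -0.18, Hspb11 0.05, Dnajb9 -1.12, Fcgr3 4.15, Cdh5 2.69 and Ecscr -1.28 in liver. With transcripts of at least 300 bases they were Tob1 -0.13 in embryos, and Fibp -1.40, Snx20 -1.67, Zmat2 -0.48, Sdhaf4 -0.29, Hspb11 1.04 and Ecscr -1.27 in liver. With status OK only they were Rnf213 1.21 in embryos, and Bid -1.36, Tfrc -0.31, Nusap1 -5.58 and Hspe1 -1.69 in liver. With isoforms weighted by length they were Krt19 0.10 in embryos, and Nostrin -0.34, Bid -1.61, Dnajb9 -0.20, Ecscr -0.18 and Hspe1 -0.12 in liver.

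Depth is among the limits of the embryo values, beside the chromosomes they cover and the scaling. The median distance to the bound for genes from 1 to 5 FPKM was 19.5% in the embryo Adar1-/- library against 10.2% in the liver library of that label. No paired analysis was possible because each group has 1 library.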

Other observations

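The genes in this part were chosen after their values were seen, and no explanation was tested for them. Several interferon-stimulated genes that were lower in the embryo Adar1-/- Mavs-/- library lie near each other on chromosome 11 (mm9), others such as Xaf1, Lgals9, Ifi35, Lgals3bp and Rnf213 lie elsewhere on it, and clustering was not tested. From 48675470 to 48910476, Irgm1 had 69.9 FPKM in the Adar1-/- library and 0.584 in the other, Tgtp1 had 9.36 and 0.00818, Tgtp2 had 8.50 and 0.00822, and Ifi47 had 6.97 and 0.247. From 58013058 to 58036282, Igtp and its neighbour Irgm2 had log2 ratios of -4.55 and -3.30. These genes encode GTPases induced by interferon, and Tgtp1 and Tgtp2 are near-identical copies that can share reads.

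Schlafen genes, a further family induced by interferon, lie from 82764851 to 82884180 and were lower as well, with log2 ratios of -2.20 for Slfn9 and -1.93 for Slfn2, while Slfn5 had 5.85 FPKM in the Adar1-/- library and was listed at 0 in the other. Among the chemokine genes nearby, Ccl2 and Ccl12 were at -1.06 and -1.23, while Ccl9, from 83386421 to 83392138, was at 0.73, with 1.98 FPKM in the Adar1-/- Mavs-/- library. The ratio of Ccl9 was not read under other scalings. These shift embryo log2 ratios by -0.94 to 0.14 before the pseudocount, and by less for genes with low values such as Ccl9.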
